A study of Drosophila melanogaster with 4 samples.

How the data were processed

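The series is a chromatin immunoprecipitation and sequencing (ChIP-seq) study of the histone variant H2Av in heads of adult Drosophila melanogaster of the wild-type Oregon-R strain. Per the labels' protocols, heads were sieved from whole flies, the homogenized tissue was crosslinked with formaldehyde, chromatin was released and fragmented by SDS and sonication, and it was precipitated with the antibody. The 4 libraries are 2 ChIP replicates made with an antibody named 9751 and 2 inputs, which the labels tie to the ChIP replicates one to one. The labels number the replicates but do not say whether they came from separate fly populations, so the spread between them may be technical.

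The values used were 3 lists of enriched regions, called clusters by the authors: 1 list per ChIP replicate, each made against its own input per the labels, and 1 combined list for the set of replicates. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, and coordinates are on FlyBase release 5, per the file headers. The caller of the clusters, its window, its threshold and the way the replicates were combined are not given in the sources used here. Each deposited cluster has a start, an end and 1 score from the authors. No header names the scale of that score, so it served to rank and filter clusters, and where scores are averaged or compared between lists, both lists are assumed to share 1 scale. The smallest cluster was 1301 bp in both replicate lists and 1001 bp in the combined list. The lists give no read counts, so the sequencing depth is unknown, no counting interval can be given, and a region outside the clusters is one that was not called, not one shown to lack H2Av. The input libraries were not analysed here except through these calls.

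The lists were read with pandas 2.3.3 under Python 3.11.15 and analysed with numpy 2.4.6 and scipy 1.17.1. Lengths of arms and scaffolds came from the file headers. Coverage is the length inside clusters divided by the length of the arm or scaffold. Values of the 2 replicates are given with their mean and SD, and no test was made between arms. Overlap between replicates meant at least 1 shared bp. Its test was a one-sided permutation test with 100000 draws, in which the clusters of replicate 1 were shifted by a random distance around each arm or scaffold, which keeps their number, widths and spacing. This p-value concerns placement along the genome in these 2 libraries, not the spread between fly populations. Tested on simulated lists of 6245 clusters, with 200 draws each, the procedure called 0 of 20 lists in which no cluster was kept in place, and 20 of 20 lists in which 25% were kept in place. The other clusters were placed at random along each arm, so these simulations do not cover lists that share only their regional density. Scores were compared across overlapping clusters by correlation, with no p-value, because clusters are not independent replicates.

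These tests, the rule for named regions and the alternatives not named below as added later were fixed before the data were examined. The rule names the 10 matched clusters with the highest mean score, the 10 widest matched clusters and the 10 longest stretches of the 5 major arms without a cluster in either replicate. Analyses of 1 Mb windows and of the 1 Mb at the centromere end of each assembled arm were added after the data had been seen. So were those of stretches against random spacing and of the medians of shared and unshared clusters after random shifts. The alternatives for the longest stretch and for the shift distance (20 kb to 200 kb) were also added then. Alternatives covered the upper 50% of each list by score, the combined list, each replicate alone, the overlap rule, the joining of neighbouring clusters, the arm length and the measure of density.

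Gene-level results had been planned (the share of clusters at transcription start sites, the share of genes marked, and marking of fixed lists of neuronal, photoreceptor, glial, clock, housekeeping, developmental, germline and other genes). They were not run: the gene table at hand is on release 6 of the genome, the clusters are on release 5, and coordinates were not moved between releases. Regions are therefore given by coordinates alone, and whether they lie in genes, exons, introns or untranslated regions was not analysed here.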

Results

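Heads of adult wild-type flies were profiled for H2Av, the histone H2A variant of Drosophila, which fills the roles that H2A.Z and H2A.X have in other animals. There were 2 ChIP replicates, each with its own input. The replicate lists held 6778 and 6672 clusters, a mean of 6725 ± 74.95 (SD, n = 2). They covered 33.0 Mb and 31.3 Mb, or 32.2 ± 1.16 Mb (SD, n = 2), which was 23.0 ± 0.829% of the assembled arms and scaffolds other than Uextra, the set of unplaced sequence in which no list had a cluster. The median cluster was 3107 ± 8.49 bp wide. Broad clusters made up much of the covered length: the 749 and 650 clusters over 10 kb held 36.8% and 32.8% of it. The read depth behind the lists is unknown.

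The first comparison asked whether the replicates placed H2Av in the same parts of the genome. They shared 25.9 Mb, which was 78.6% of the length called in replicate 1, 82.8% of that in replicate 2 and 67.6% of the length called in either. When the clusters of replicate 1 were shifted at random along each arm, the shared length was 8.17 ± 0.283 Mb (SD over 100000 draws), with a highest draw of 12.6 Mb. The observed overlap was 3.18 times that mean, with a one-sided permutation p of 1e-05, the smallest that the draws can give. By number, 76.2% of replicate 1 clusters and 81.4% of replicate 2 clusters touched a cluster of the other list, against 36.8 ± 0.931% of shifted replicate 1 clusters (permutation p = 1e-05).

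Clusters found in 1 replicate alone were narrow and low in score. In replicate 1 the 5164 shared clusters had a median width of 3881 bp and a median score of 1.05, whereas the 1614 unshared ones had medians of 1702 bp and 0.815. In replicate 2 the 5430 shared clusters had medians of 3656 bp and 1.12, and the 1242 unshared ones of 1650 bp and 0.814. Wide clusters touch another list by chance more often: in 1000 random shifts of each list the unshared clusters had mean medians of 2823 bp and 0.938 in replicate 1 (lowest draw 2675 bp and 0.915) and of 2883 bp and 0.976 in replicate 2 (lowest draw 2666.5 bp and 0.942). Part of the contrast with shared clusters thus follows from the overlap rule. Across the 5164 overlapping pairs, the scores of the 2 lists correlated with a Spearman rho of 0.69 and a Pearson r of 0.69. The widths correlated with a rho of 0.64 and an r of 0.62. These are correlations across clusters, which are not independent replicates. Score also rose with width within each list (rho of 0.63 and 0.73 across clusters).

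The distribution over chromosomes was uneven. Chromosome 4, the small dot chromosome known for interspersed heterochromatin, had the highest coverage of any chromosome or scaffold in the assembly: 60.4% in replicate 1 and 45.4% in replicate 2, or 52.9 ± 10.6% (SD, n = 2). This was 2.09 ± 0.443 times the coverage of the 4 large autosomal arms pooled, and 27.5 ± 10.9 percentage points above it. Among those arms, 2R was covered most (31.4 ± 0.872%), followed by 3R (24.6 ± 0.787%), 3L (23.6 ± 0.196%) and 2L (22.7 ± 0.138%). The gap between 2R and each other autosomal arm was larger than the SD of the replicates. Clusters on chromosome 4 were also more closely set, with 88.0 and 76.2 per Mb against 50.8 and 53.5 per Mb on the autosomal arms.

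The X chromosome did not differ from the autosomes in one direction. Its coverage was 25.8% in replicate 1 and 21.3% in replicate 2, which was 1.03 times and 0.832 times that of the autosomal arms (0.930 ± 0.138, SD, n = 2). The difference in percentage points was 0.70 in replicate 1 and -4.30 in replicate 2, so its direction rests on which replicate is read. The autosomal arms were covered about equally in both lists, at 25.1% and 25.6%.

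The scaffolds of assembled heterochromatin were covered less than the large arms as a whole but varied widely. Coverage was taken over their full length, and sequence gaps and repeats in them were not examined. Low coverage on a scaffold therefore need not mean little H2Av. The 5 scaffolds assigned to chromosomes 2, 3 and X were together covered to 17.7% in replicate 1 and 10.9% in replicate 2, or 0.565 ± 0.196 times the autosomal arms. XHet stood highest at 47.1 ± 7.87%, followed by 2LHet at 35.8 ± 5.83%. The values were 17.6 ± 5.73% for 3LHet, 12.5 ± 4.55% for 2RHet and 7.45 ± 3.72% for 3RHet. The unplaced scaffold U was covered to 3.51 ± 1.91%. On YHet, the Y-linked scaffold, coverage was 1.10 ± 0.737%; replicate 1 had 4 clusters and replicate 2 had 1, with no shared base. On the heterochromatic scaffolds 42.3% of the length called in either replicate was called in both, against 70.1% on the autosomal arms. Independent placement at these coverages would give 9.75% and 14.8%, and the unequal lengths of the 2 lists limit the share to at most 61.8% and 98.1%.

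**Figure D1:**
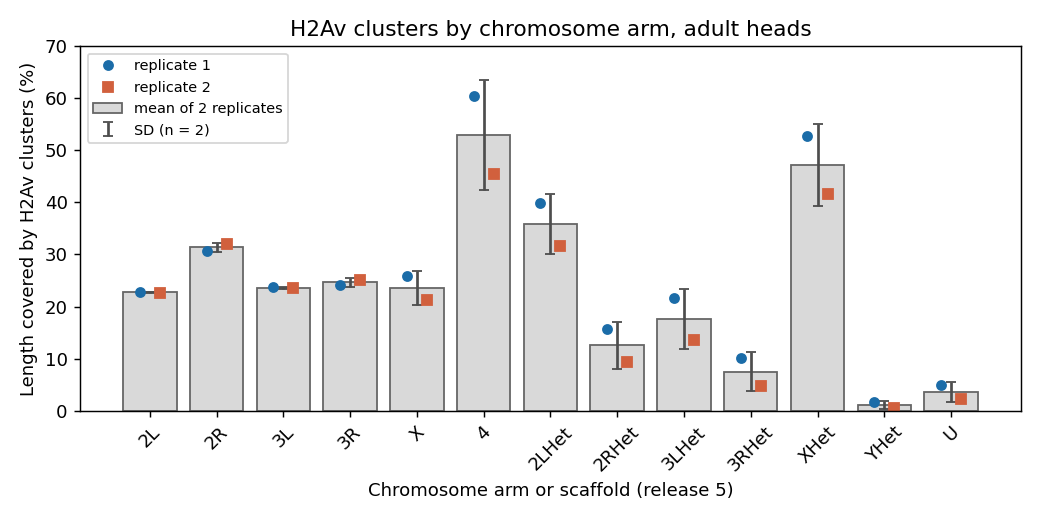
Length of each chromosome arm or scaffold inside H2Av clusters, in percent (y axis), for the large arms, chromosome 4, the heterochromatic scaffolds (Het) and the unplaced scaffold U (x axis). Bars are means of 2 replicates, error bars are SD, and circles and squares are replicates 1 and 2; chromosome 4 stands highest at 52.9%, and its 2 replicates also lie furthest apart.

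Along the large arms, H2Av coverage followed the same regional profile in both replicates. Over 119 windows of 1 Mb, coverage in replicate 1 and replicate 2 correlated with a Spearman rho of 0.94 and a Pearson r of 0.95, across windows. Within single arms rho lay between 0.95 on X and 0.99 on 2R. The most covered window was 2L from 22000001 to 23000000, at 57.1 ± 4.25% (SD, n = 2), followed by 2R from 1 to 1000000 (56.4 ± 4.10%) and 2R from 1000001 to 2000000 (49.5 ± 0.214%). Next came 3L from 23000001 to 24000000 (46.6 ± 4.57%) and 3R from 20000001 to 21000000 (43.6 ± 0.427%). The least covered window was 2L from 14000001 to 15000000, at 3.27 ± 0.222%. Low coverage was also found on 3L from 10000001 to 11000000 (5.37 ± 0.233%), on 2L from 17000001 to 18000000 (5.78 ± 0.0122%), on 3L from 22000001 to 23000000 (9.93 ± 0.743%) and on 2L from 15000001 to 16000000 (10.0 ± 0.0723%). The 5 highest and 5 lowest windows were chosen after the values had been seen.

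The proximal 1 Mb, at the centromere end of each assembled arm, differed between arms. The heterochromatic scaffolds are assembled apart from the arms, so these windows need not adjoin the centromere itself. On 2L it was covered to 57.0 ± 4.33%, against 21.1 ± 0.0521% for the rest of the arm, a ratio of 2.70 ± 0.212 (SD, n = 2). The ratio was 1.88 ± 0.206 on 2R and 1.56 ± 0.223 on 3L. On 3R it was 1.14 ± 0.0768. On X the direction was opposite, with 15.5 ± 3.68% in the proximal 1 Mb, 24.0 ± 3.18% elsewhere and a ratio of 0.641 ± 0.0686. Each of these directions was the same in both replicates. On 3L, however, the part of the window from 24000001 to the end of the arm was covered to 27.1% in replicate 1 and 18.3% in replicate 2. The rest of the arm outside the window was at 23.1% in both, so most of the higher coverage on 3L lay in the part further from the centromere. The windows were chosen after the data had been seen, and no test was made.

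**Figure D2:**
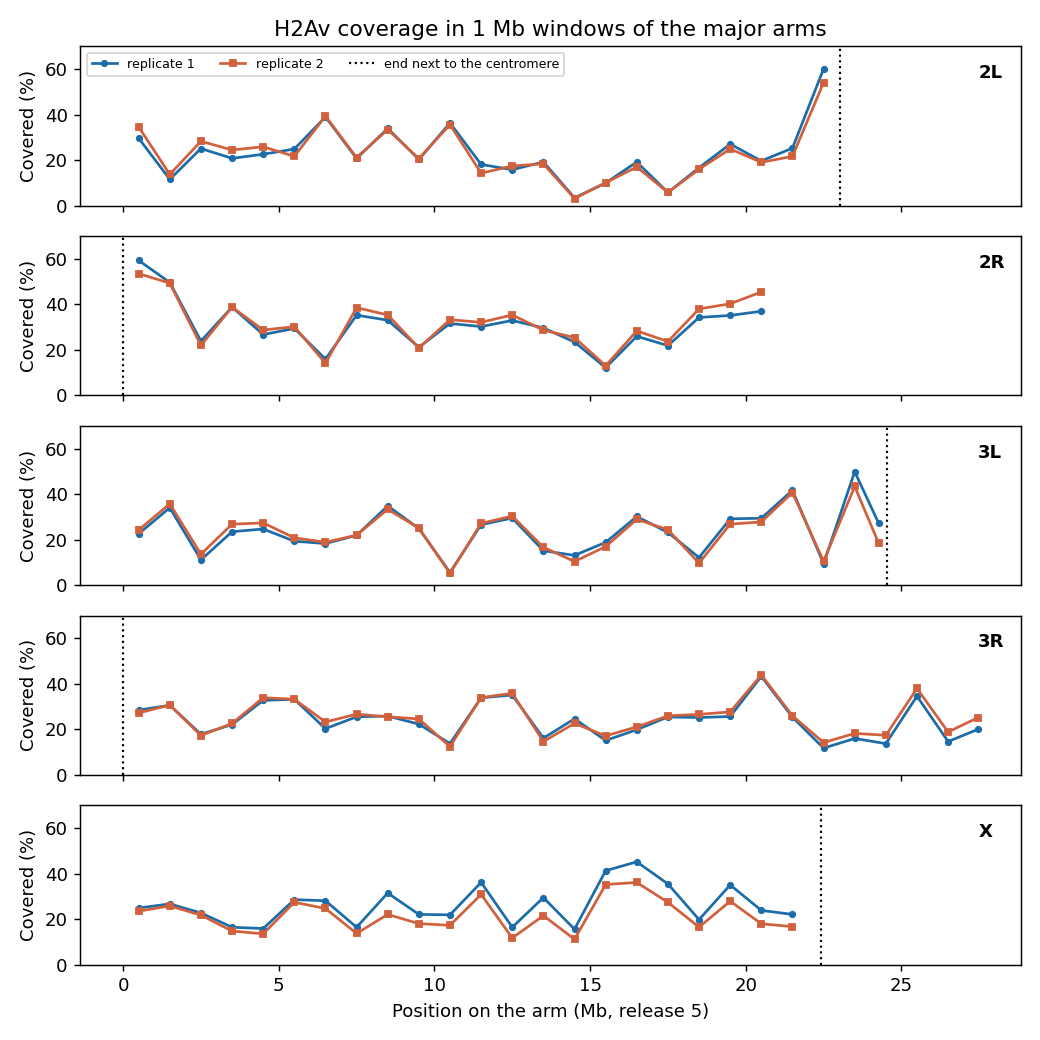
Percent of each 1 Mb window inside H2Av clusters (y axis) against position on the 5 large arms in Mb on release 5 (x axis), with replicate 1 as circles and replicate 2 as squares. The dotted line marks the end of the assembled arm on the side of the centromere. The window at that end is the most covered one on 2L (57.1%) and 2R (56.4%), and 2L falls to 3.27% in its lowest window, which ends at 15000000.

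Of the 10 widest matched clusters, 5 were on 2R (2 of them paired with the same replicate 2 cluster), 2 on 3R, 2 on chromosome 4 and 1 on 3L. The widest pair spanned 2R from 1377293 to 1430763 in replicate 1 (53.5 kb) and from 1332837 to 1398368 in replicate 2 (65.5 kb). Further ones near that end of 2R ran from 1549470 to 1590958 (41.5 kb, 41.9 kb in replicate 2) and from 1136854 to 1174246 (37.4 kb in both). The 65.5 kb cluster of replicate 2 also matched a replicate 1 cluster from 1332529 to 1352447 (19.9 kb). The remaining one on 2R began at 7193568 (59.8 kb and 26.9 kb). On chromosome 4, the clusters from 738409 to 799221 (60.8 kb, 30.9 kb in replicate 2) and from 163711 to 204054 (40.3 kb, 32.8 kb in replicate 2) were among the widest. On 3R neighbouring clusters from 4077938 to 4107201 (29.3 kb, 44.6 kb in replicate 2) and from 4114548 to 4171606 (57.1 kb, 31.0 kb in replicate 2) both ranked among the 10. The cluster on 3L ran from 16562391 to 16610649 (48.3 kb, 28.1 kb in replicate 2). Several of these pairs therefore differed in width between the lists, as at 2R 7193568.

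The highest-scoring matched clusters lay mostly on X. Of the 10 highest by the authors' score, 7 were on X, and 1 each on 2R, 3R and U. The highest was X from 2612818 to 2623138, with scores of 2.47 in replicate 1 and 2.80 in replicate 2. It was followed by X from 9125132 to 9131617 (2.55 and 2.38), X from 13503044 to 13508396 (2.25 and 2.62) and X from 20282806 to 20292704 (2.33 and 2.48). The highest on an autosomal arm was 2R from 708732 to 719054 (2.49 and 2.32), then 3R from 18564744 to 18577334 (2.05 and 2.61). The remaining X clusters began at 17742976 (2.22 and 2.37), 16196365 (2.48 and 2.10) and 10745723 (2.39 and 2.17). The cluster on U from 2096417 to 2097902 scored 3.51 in replicate 1 and 1.10 in replicate 2. All 10 of these and all 10 of the widest overlapped a cluster of the combined list, which was made from the same libraries.

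Long stretches of the arms had no cluster in either replicate. The longest was 607 kb on 2L from 14364764 to 14972227, and the next was 557 kb on 2R from 15566122 to 16122837. These were followed by 3L from 22287834 to 22680525 (393 kb), X from 11950421 to 12329226 (379 kb), 3L from 18108891 to 18452412 (344 kb) and 3R from 23794590 to 24138065 (343 kb). The rest of the 10 longest were X from 7237781 to 7570992 (333 kb), 3L from 13044942 to 13369186 (324 kb), 2L from 3874187 to 4177610 (303 kb) and X from 2685146 to 2972439 (287 kb). In total 182 such stretches exceeded 100 kb and made up 25.7% of the large arms. The combined list placed at most 2 clusters in each of the 10 and none in the 3L stretch from 22287834 or the 2L stretch from 3874187. Sequence gaps and repeats in these stretches were not examined.

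The authors' combined list held 7576 clusters over 38.2 Mb. It contained 99.9% of the length called in both replicates and 73.7% of the length called in only 1. Of its own length, 67.8% was called in both replicates, 14.5% in replicate 1 alone, 9.55% in replicate 2 alone and 8.19% in neither. It also held 1203 clusters, 15.9% of its number, that touched no cluster of either replicate. These had a median width of 1199 bp, against 3469 bp for its other clusters. Part of this contrast may follow from unlike smallest widths, which were 1301 bp in the replicate lists and 1001 bp in the combined list. With the combined list, coverage was 59.4% on chromosome 4, 29.4% on X and 29.7% on the autosomal arms.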

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

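The results for windows and for the centromere ends of the arms, with all their alternatives, were chosen after seeing the data. So were the alternatives for the longest stretch and the shifts of 20 kb to 200 kb. Keeping only the upper 50% of each list by score left 3363 clusters of median width 5074 bp over 23.4 Mb, because score rises with width, and moved the ratio of X to autosomal coverage to 1.10. The combined list covered 38.2 Mb with a median width of 2909 bp. Counted as clusters per Mb, chromosome 4 stood at 1.58 times the autosomal arms. The score correlation was 0.77 for pairs with reciprocal 50% overlap and 0.64 for widths in place of scores. The cause of these shifts was not tested except where stated. The overlap of replicates kept its direction and a permutation p of 1e-05 in every alternative run: the percent of length in both lists lay between 64.4 for the upper 50% and 69.5 for the major arms, and the percent of replicate 1 clusters touching replicate 2 between 67.7, with at least 50% of the cluster's length required, and 80.3 on the major arms. Shifts of 20 kb to 200 kb keep regional density and gave a higher chance level, with an observed-to-shifted ratio of 2.68. Each replicate alone gave a ratio above 1 for chromosome 4 and below 1 for the heterochromatic scaffolds, while X gave 0.832 without replicate 1 and 1.03 without replicate 2. The longest stretch without a cluster, 607 kb, was 638 kb without replicate 1 and in the upper 50% by score, 608 kb without replicate 2 and 556 kb in the combined list. With windows of 2 Mb the ratio at the centromere end of 2L was 1.91. In the upper 50% by score, the ratio at the centromere end of 2R was 2.18, against 1.88 in the full lists. The Spearman correlation of 1 Mb windows was 0.889 there, against 0.942 in the full lists. The planned results on start sites, marked genes and gene lists were not run, because the gene table is on another release. No paired analysis was possible because the inputs that share the replicate numbers have no values of their own in the lists. Depth is unknown, and its effect on narrow clusters cannot be read from these lists. The 1203 clusters of the combined list found in neither replicate had a median width of 1199 bp. The smallest cluster was 1301 bp in each replicate list but 1001 bp in the combined list, so most of them were narrower than any replicate cluster. The combined list raised the covered length to 38.2 Mb, of which 3.13 Mb was called in neither replicate.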

Other observations

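Of the tests in this part, those on the score floor of narrow clusters and on the pooled proximal windows were written down before their results were seen, and the others were chosen after seeing the data. Clusters on X scored high for their number. X held 805 of the 5164 matched clusters (15.6%), against 4045 on the autosomal arms, but 40 of the 100 with the highest mean score. It makes up 18.8% of the length of the large arms. That share leaves out chromosome 4 and the scaffolds, whose clusters are among the 5164, so it is not on the same base as the 15.6%. Within each list the median score was higher on X than on the autosomal arms, at 1.12 against 0.908 in replicate 1 and 1.14 against 0.984 in replicate 2.

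Replicate 2 covered less of X than replicate 1 (0.825 times), and also less of chromosome 4 (0.753 times) and of the heterochromatic scaffolds (0.618 times). The proximal 1 Mb of each autosomal arm was also less covered in replicate 2. In replicates 1 and 2 it was at 60.1% and 54.0% on 2L, 59.3% and 53.5% on 2R, 39.7% and 32.5% on 3L, and 28.5% and 27.2% on 3R. The rest of each of these arms was covered no less in replicate 2. Coverage was not lower across the whole of replicate 2: on the autosomal arms it was 1.02 times that of replicate 1, and no arm fell below 0.988 times. This cannot decide on stricter calling or lower depth in replicate 2, because coverage depends on enrichment as well as on the cut. The 5th percentile of scores of autosomal clusters up to 2000 bp was in fact higher in replicate 2 (0.493 against 0.386). A few repeat-rich stretches of X called in replicate 1 alone are argued against by the windows, since 100% of the 22 X windows of 1 Mb were less covered in replicate 2. Fewer reads from X in replicate 2 would be expected to raise the lowest scores called there. The 5th percentile of scores of X clusters up to 2000 bp did not rise: it was 0.558 in replicate 1 and 0.526 in replicate 2. It exceeded that of autosomal clusters by 0.172 in replicate 1 and 0.033 in replicate 2, a change of -0.139. The 95% bootstrap interval, over clusters within these libraries, was -0.218 to -0.059. Most of this change was the rise on the autosomal arms, and the X value itself changed little. This reading assumes that the score is an enrichment over input. By the same reading, the gap in replicate 1 would mean fewer reads from X in the list that covered more of it. The lowest scores may also follow the higher scores of X clusters in both lists, so they cannot decide on the number of reads. A shift of ChIP over input along the whole of X in replicate 1 stays open. Matched X clusters had a median percentile rank by score that was 10.9 points higher in replicate 1 than in replicate 2 (95% bootstrap interval over clusters 8.29 to 13.8), but such ranks are relative to the other clusters, and score rises with width, so they partly restate the difference in coverage. The ranks were also higher in replicate 1 on chromosome 4 (26.9 points) and on the heterochromatic scaffolds (17.2 points), so the rise was not particular to X. The median score itself was not higher on X in replicate 1 (1.23 against 1.25 in replicate 2, difference -0.021, interval -0.058 to 0.022), while on the autosomal arms it was lower in replicate 1 (difference -0.205) and on chromosome 4 it was higher in replicate 1 (0.183, interval 0.082 to 0.355).

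The high coverage of the proximal 1 Mb of 2L, 2R and 3L could come from chance calls in repeats that differ between libraries. The percent of called length found in both lists, pooled over the 3 windows, was -1.67 points from the rest of the arms, a comparison fixed before its result was seen. That comparison decides little, because the share rises with coverage alone: independent placement would give 39.7% in the proximal 1 Mb of 2L, 39.1% in that of 2R and 21.8% in that of 3L, but 11.8, 17.7 and 13.1% in the rest of these arms. The arms were therefore taken apart, and each share was set against the one expected if the coverage above the rest of the arm came from calls placed independently in each list. On 2L the share was 69.3% (69.4% in the rest of the arm), 22.7 points above the 46.5% expected (95% interval 15.1 to 29.9, bootstrap of 50 kb blocks), and on 2R it was 79.5% (71.8% in the rest), 28.7 points above the 50.8% expected (21.7 to 33.4). Blocks of 100 kb also gave intervals above 0 on these 2 arms. That expectation spreads the calls over the whole window, and only such evenly spread chance calls are argued against as the whole cause. Calls confined to repeats would share more, and repeats were not located, so chance calls in repeats stay open on 2L and 2R. On 3L chance calls of either kind are a candidate explanation. The share there was 52.0%, against 68.4% in the rest of the arm. It was 7.80 points from the 44.2% expected, with an interval of -18.0 to 20.2. Repeats themselves were not examined, and no biological explanation was tested.

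The long stretches without clusters are a hypothesis about broad organisation. The longest, 607 kb, lay above the longest stretch in each of 10000 placements with the same number of clusters per arm and random gaps, which ranged from 87.6 to 247 kb with a median of 123 kb. Random spacing of clusters along each arm is thus argued against. The coverage of 1 Mb windows, from 3.27% to 57.1%, had already shown that spacing is uneven, so this adds no separate support for broad organisation. Sequence gaps and gene-poor regions could not be examined.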
